A study of Zea mays with 27 samples.

How the data were processed

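Maize seedlings of the inbred lines B73 and Mo17 and of their F1 hybrid, made with Mo17 as the seed parent, were profiled on 2-colour cDNA microarrays. Per the labels, above-ground tissue was taken at 14 days and 6 seedlings were pooled for each genotype in each replication. The series' design text describes 10 replications grown in randomized blocks, of which 1 was removed for poor quality and 9 were kept. Each kept replication had 3 arrays that joined the 3 genotypes in a loop of pairwise hybridizations, with the dyes alternated, which gives 27 arrays. Channel 1 was Cy3 and channel 2 was Cy5 on each array, per the labels. The labels used here name the genotype of 1 channel on 1 array, S1 (F1 in Cy3), and of no other channel. The 27 arrays were therefore left without a group, and no comparison of B73, Mo17 and F1 was made.

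The deposited values, 1 per spot and array, were read as natural log ratios of the channels. The base of the logarithm was inferred from the values, after they were seen. Values repeated at least 3 times on an array lay 2 times the natural log of a whole number from 2 to 10 apart (tolerance 2e-05) in 106 pairs, against 4.56 at shifted distances. The numbers for base 2 were 3 against 3.67 pairs, and for base 10 they were 20 against 20.8. Only distances of 2 times the log were tried, so the check chose among these bases and did not exclude a constant multiple of the log ratio. All values were divided by the natural log of 2, so that results are on the log2 scale if this reading holds. Fold values rest on it too. Array medians of the deposited values ran from -0.23 (S20) to 0.28 (S15) on that scale. The scanner software, background correction and normalization are not given in the sources used here. Which channel is the numerator is not stated either, so signs have no settled meaning and are given only as above or below the array's median.

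The table had 19200 spots, of which 897 were empty on each array. The other 18303, called probes here, had a value on all 27 arrays. Each array was centred on its median. The spread of a probe was the distance from the 10th to the 90th percentile of its centred values over arrays, and probes with a spread of at least 1 (2-fold) were counted among those valued on at least 20 arrays. A probe had 1 sign when at least 90% of arrays lay on the same side of the array median, which takes 25 arrays. For structure, each probe's median was removed, and Pearson correlations of arrays across probes and principal components were computed. Counts were set beside values shuffled over probes within each array, or with signs turned at random. A gene list was described by the median spread of its probes, its ratio to the median of all gene-named probes, and its percentile among 10000 random lists of the same size drawn from gene-named probes. A list was set apart when its percentile was at most 2.5 or at least 97.5. Such percentiles describe these arrays and are not a test of genotypes. Since no intensity was used and all probes had a value on all arrays, the lists could not be matched on signal in advance.

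Gene names came from the platform's gene table, updated through gene identifiers in RefSeq's annotation of the assembly Zm-B73-REFERENCE-NAM-5.0, from which no coordinates were used. Of 1630 probes in the table, 23 had several genes and were not named, and 1607 had 1 gene, for 532 genes in all. RefSeq held 1320 of these probes and 515 of the genes. A further 16673 probes are unnamed here. The name MNB1b stands on 221 probes and is uncertain. Both tables give symbols and synonyms without descriptions, so the 18 gene lists matched symbols and synonyms only. Of these lists, 11 had at least 3 probes, 2 had fewer and 5 had 0, namely ribosomal proteins by description, flavonoids, ubiquitin and proteasome, transposable elements, and lipid transfer proteins. Ribosomal proteins and translation factors were then matched by symbol, a choice made after the names were seen.

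Genes were named by a fixed rule. It takes the 25 gene-named probes with the widest spread, up to 5 at each end of the median among gene-named probes with 1 sign, and the 3 widest probes of each list. It takes probes, so other probes of the same gene are given beside several of them, a choice made after the values were seen. The agreement of probes of the same gene was analysed after the data were seen, as the mean Pearson correlation over pairs of probes of each gene, with gene names shuffled over probes 1000 times. Genes named for it were chosen after their values were seen.

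Further features were found in the values and used only for alternatives and checks. Arrays were divided by whether at least 2% of spots held the array's most frequent value, which gave 15 and 12 arrays. Runs of 400 spots in table order were taken as 48 printing blocks, because empty spots recurred at that distance in 83.3% of cases, against at most 63.1% for the other distances among 21 tried. Both readings are inferences from the values. The number of arrays limits the precision of all results.

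The steps were tested on simulated data made from the real values with random signs. A parental difference of 1 on the log2 scale, with the hybrid midway and 9 simulated loops, was added to 100 probes. Their median spread went from 1.58 to 2.30, and 77.0% of them had a spread of at least 1 before the addition and 100% after it. With a difference of 2, the median spread of another 100 probes went from 1.92 to 3.90. Neither difference gave 1 sign in any of these probes (0%), but each simulated loop held effects of both signs by construction. An offset of 0.5 shared by all arrays was found as 1 sign in 22.0% of 100 probes, and an offset of 1 in 63.0%. When all probes of a gene carried a parental difference of 1, 52.0% of 50 genes reached an agreement of 0.5, and 94.0% of another 50 did so at a difference of 2. Of 400 random lists of 20 probes, 4.00% reached the 97.5th percentile, against 84.5% of lists whose spreads were multiplied by 1.5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were the centring and scale of arrays, the minimum number of arrays, the measure and threshold of spread, each array left out, block centring, repeated values as missing, each set of arrays alone, random lists matched on repeated values, and lists with 1 value per gene.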

Results

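The study asked how gene expression in the F1 hybrid of Mo17 and B73 maize related to that of its inbred parents in above-ground seedling tissue. The 27 arrays, S1 to S27, each gave 18303 log ratios between 2 genotypes that the labels used here do not name. The values below therefore describe how far named genes varied from array to array, and none is a comparison of B73, Mo17 and F1. The arrays are not replicates of a group, so no error of a mean is given.

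The arrays differed widely in the size of their ratios. Over arrays, the interquartile range had a median of 0.75 on the log2 scale and ran from 0.40 (S9) to 1.57 (S19). The share of probes at least 2-fold from the array's median had a median of 17%, from 4.64% (S17) to 39.1% (S19). On S1 to S15, between 452 (S1) and 2545 (S3) probes held the array's single most frequent value, and on S16 to S27 between 11 (S19) and 87 (S25) did. Medians of the 48 blocks of spots had an SD from 0.0792 (S22) to 0.76 (S15) within an array.

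**Figure D1:**
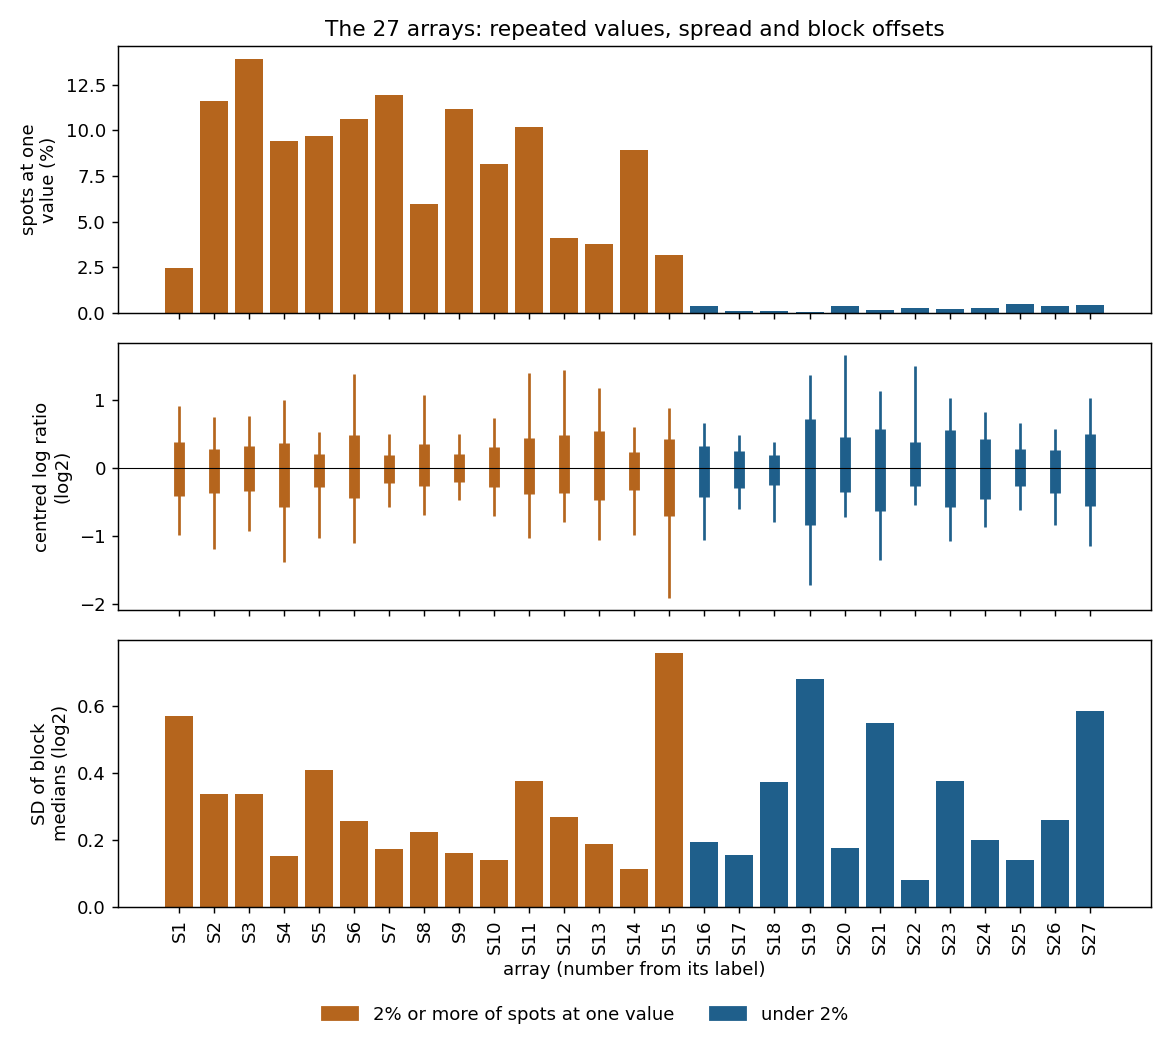
For each of the 27 arrays (horizontal axis), the upper panel gives the percent of probes at the array's most frequent value, the middle panel the interquartile range (thick) and the 10th to 90th percentile range (thin) of centred log2 ratios, and the lower panel the SD of block medians in log2 units. S1 to S15 (brown) had between 2.47% and 13.9% of probes at 1 value, S16 to S27 (blue) between 0.0601% and 0.475%, and S19 had the widest interquartile range, 1.57.

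The gene-named probe with the widest variation was 1 of LOC542602 (synonym hsp22), a small heat shock protein, whose spread from the 10th to the 90th percentile over arrays was 7.79 on the log2 scale. The gene's other probe had a spread of 0.79. Values below are those of single probes. A probe of another small heat shock gene, LOC542293 (hsp18a), had a spread of 5.36, and the gene's other probes had 1.82 and 2.53. Cell wall genes had probes in this group of 25, with LOC541807 (CesA-9) at 6.10 and LOC541806 (cesa8) at 5.13, both cellulose synthase subunits. The other 2 probes of CesA-9 had 2.01 and 2.82, and the other 7 of cesa8 ran from 0.86 to 3.09 with a median of 1.01. The wall glycoprotein gene LOC542371 (HRGP) had a spread of 6.41, against a median of 1.44 over its other 7 probes, and LOC541793 (Bk2L3), of the brittle stalk family, had 6.27. The MADS-box genes LOC542244 (ZAG1) and LOC542256 (bde1, also ZAG3), known from floral development, reached 5.68 and 4.98.

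Signalling and regulatory genes in the group were LOC541642 (hk3), a histidine kinase, at 6.14, LOC542702 (PLD1), a phospholipase D, at 5.31, LOC732738 (WRKY1), of a transcription factor family, at 4.99, and LOC542240 (tbp1), a TATA-binding protein, at 6.60. Metabolic and transport genes were LOC541833 (gst18), a glutathione transferase, at 6.04, LOC542661 (SPP2), a sucrose-phosphate phosphatase, at 5.93, and LOC542571 (pox2), a peroxidase, at 5.46. LOC541800 (ys1), the iron-phytosiderophore transporter, had 5.04, and LOC542166 (4CL), which activates coumarate for lignin synthesis, had 4.91. Genes known from the endosperm were LOC542570 (betl2), at 5.89, and LOC100125634 (meg2), at 4.92. The other members were LOC606472 (derlin4) at 7.05, LOC542474 (HINT) at 6.74, M8 at 5.21, LOC100125654 (rnc1), a chloroplast splicing factor, at 5.15, LOC606423 (aprl8) at 5.07, and LOC542597 (piip1) at 4.97.

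For 12 of the 25 genes there were 29 other probes with a median spread of 1.31. None was as wide as its gene's probe among the 25, which the choice of the widest probes fixed in advance, since the 25 were of 25 genes. Where not given above, the other probe had 1.05 for HINT, 3.85 for pox2 and 1.49 for M8. It had 1.94 for aprl8, 2.21 for piip1 and 1.18 for 4CL, and the other 4 of WRKY1 had a median of 0.85. Of the 25 probes, 20 held an array's most frequent value on at least 1 array, and 5 did not, namely those of PLD1, M8, cesa8, aprl8 and WRKY1. The probes of derlin4, 4CL, meg2, ZAG1 and gst18 held it on 16, 15, 13, 13 and 12 arrays, so that their values within S1 to S15 were mostly a repeated constant. For derlin4 the spread was 0.19 within S1 to S15 and 8.46 within S16 to S27, for 4CL it was 0.09 and 9.12, and for meg2 it was 0.19 and 8.31. For ZAG1 it was 0.19 and 6.39, and for gst18 it was 0.31 and 7.39. PLD1, never at that value, had 6.89 within S1 to S15 and 0.74 within S16 to S27. In both sets alone, 19 of the 25 kept a spread of at least 1.

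Among all 18303 probes, 14493 (79.2%) had a spread of at least 2-fold, 6592 of at least 4-fold and 1288 of at least 16-fold. Gene-named probes had a spread of at least 2-fold in 1045 of 1607 cases (65%). The median spread was 1.54 over all probes (quartiles 1.06 and 2.52) and 1.17 over gene-named probes. Shuffling values over probes within each array gave 17895 probes of at least 2-fold and a median spread of 1.73. Shuffling mixes wide and narrow probes and so raises a count at this threshold, which makes it no test of an excess. The 4117 probes at the most frequent value on at least 1 array had a median spread of 3.04, and the other 14186 had 1.31. The count was 4617 when the interquartile range replaced the percentile distance.

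Iron and nicotianamine genes had the widest spread of the lists, with a median of 4.50 over 3 probes, 3.84 times that of all gene-named probes. They were the probe of ys1 and a pair of probes of LOC542480 (nas1), nicotianamine synthase, at 4.50 and 3.52, the latter with 0.86 within S1 to S15 and 3.70 within S16 to S27. This was the 99.9th percentile of random lists, and the only fixed list outside the central range set for the lists. The list held 2 genes, too few for a percentile with 1 value per gene, and probes of a gene are not independent members. All 3 probes had held a most frequent value, and among random lists matched on that the percentile was 92.8. With the interquartile range the ratio was 1.09.

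Phenylpropanoid genes had a median of 2.63 over 3 probes (percentile 97.1, or 65.4 among random lists matched on repeated values), from LOC542258 (pal3), a phenylalanine ammonia-lyase, at 3.03 and 2.63, and LOC542663 (BM1), a cinnamyl alcohol dehydrogenase, at 2.57. Cell wall growth genes had a median of 1.43 over 23 probes (percentile 95.8), of which 19 reached 2-fold. A probe of the expansin LOC542648 (expa2) had 4.25 and held a most frequent value on 7 arrays, and the gene's other probes had 0.61 and 2.39. Aquaporins, which are water channels, had 1.35 over 23 probes (percentile 90), of which 16 reached 2-fold. With 1 value per gene, the percentile was 58.4 for cell wall genes and 83.1 for aquaporins. The 2 phenylpropanoid genes were too few for it. The widest aquaporin probes were LOC541886 (PIP1-3) at 3.31, LOC542497 (Lsi6) at 3.29 and LOC541891 (PIP2-6) at 3.27.

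C4 and Calvin cycle genes had a median of 1.65 over 5 probes (percentile 89.3), and all 5 reached 2-fold. LOC542212 (rbcs1), the Rubisco small subunit, had 1.94, and LOC542233 (me3), the NADP-malic enzyme of the C4 pathway, had 1.83 and 1.65. Starch and sucrose genes had 1.40 over 17 probes (percentile 90.1), with LOC732804 (bt1), a plastid ADP-glucose carrier, at 2.63, LOC541854 (wx1), granule-bound starch synthase, at 2.07, and LOC542247 (sus1), a sucrose synthase, at 1.77. The bt1 probe held a most frequent value on 14 arrays, and its spread was 0.19 within S1 to S15 and 5.10 within S16 to S27. The wx1 probe had 1.19 after block centring, and the gene's other probe had a spread of 1.51. With 1 value per gene, the percentile was 63.8 for C4 and Calvin cycle genes, 40.1 for starch and sucrose genes and 3.56 for photosystem genes. Photosystem genes had 1.04 over 7 probes (percentile 26.9), of which 4 reached 2-fold. Their widest were LOC541685 (psah1) at 1.53, LOC542126 (psbs1) at 1.14 and LOC542605 (psan1) at 1.10.

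Stress and structural lists lay near the median of named genes. Heat shock genes had 1.26 over 24 probes (percentile 74.1), and after the pair named above their widest probe was another of hsp18a, at 2.53. Glutathione transferase and oxidative stress genes had 1.23 over 58 probes (percentile 74.8), of which 49 reached 2-fold, with LOC541841 (gst30) at 4.01 and LOC541834 (gst19) at 3.74 after gst18. The gst30 probe held a most frequent value on 13 arrays, and its spread was 0.09 within S1 to S15 and 7.06 within S16 to S27. Cytoskeleton genes had 1.16 over 45 probes (percentile 47.1), led by the tubulins LOC542416 (tub3) at 3.88, LOC542705 (tub7) at 1.76 and LOC542417 (tub4) at 1.76. The tub3 probe held a most frequent value on 10 arrays, and its spread was 1.99 within S1 to S15 and 3.93 within S16 to S27. Histones had 1.13 over 25 probes (percentile 38), led by LOC542385 (his1), a linker histone, at 2.90 and 1.46 and LOC541964 (his1a) at 1.68. Of the 25 histone probes, 18 were of LOC542301 (his2b5). With 1 value per gene, the percentile was 71.9 for 4 heat shock genes and 44.4 for 17 oxidative stress genes. It was 36.5 for 10 cytoskeleton genes and 34.9 for 3 histone genes. Lists too small for a percentile gave 2.89 for LOC542720 (pr5) and 1.77 for LOC542525 (chn1), a chitinase, among defence genes, and 2.66 for the storage protein gene gz27.

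**Figure D2:**
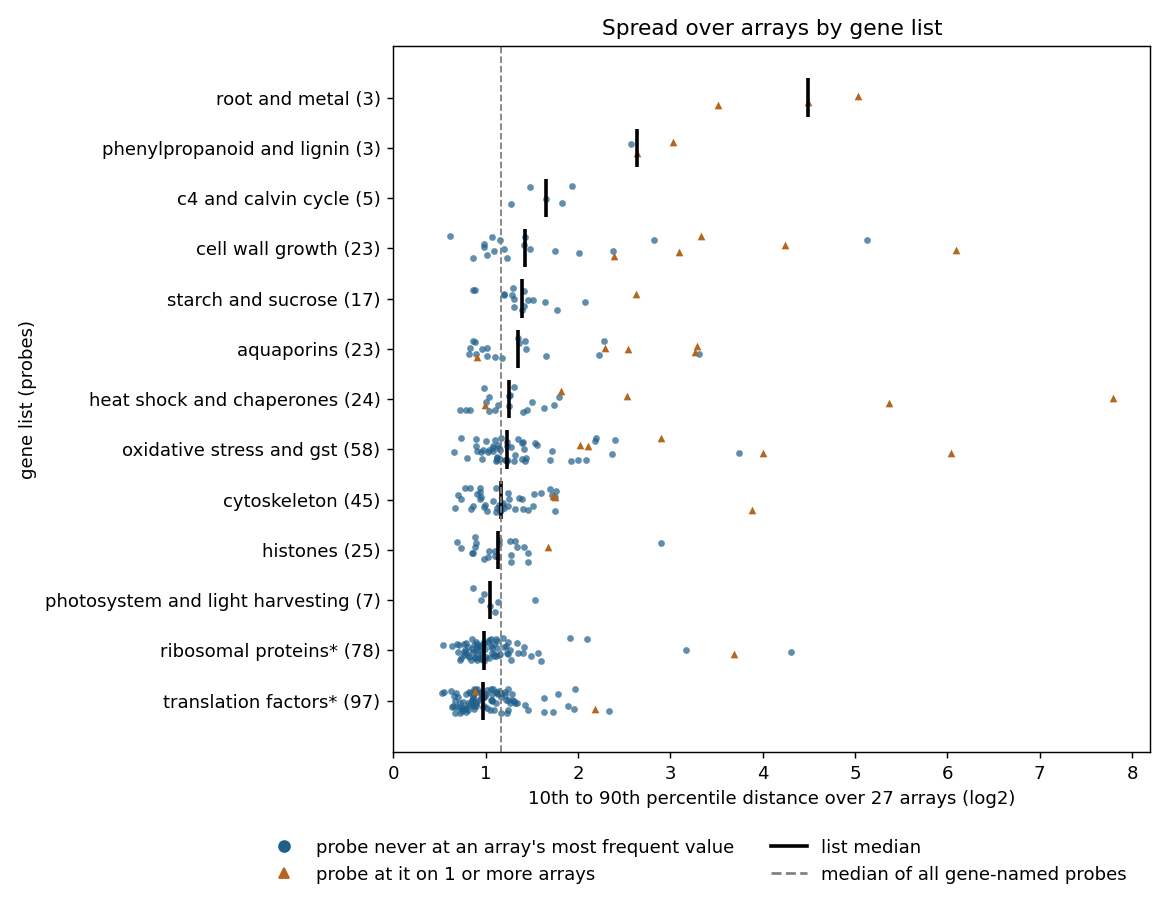
Each point is a probe, placed by its 10th to 90th percentile distance over the 27 arrays in log2 units (horizontal axis) and its gene list (vertical axis, with the number of probes), and triangles mark probes at an array's most frequent value on 1 or more arrays. Black bars are list medians, from 0.97 for translation factors to 4.50 for root and metal genes, the dashed line is the median of gene-named probes, 1.17, and asterisks mark lists matched by symbol after the names were seen.

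A probe of WRKY1 had the largest shift to 1 side among gene-named probes, with a median of 1.84 over arrays and 25 arrays above the array median. The gene's other 4 probes had medians from -0.03 to 0.08. A probe named MNB1b also lay above on 25 arrays, with a median of 0.19. Probes of LOC542094 (rop9), a small GTPase of the ROP family, and of LOC542610 had medians of -0.68 and -0.57, each below on 25 arrays. The other probe of rop9 had a median of -0.51, and the other 3 of LOC542610 had medians from -0.20 to 0.06. A probe of LOC542395 (tua3), an alpha-tubulin, lay below on 26 arrays with a median of -0.27, while the other 8 of that gene had medians from -0.10 to 0.34. Whether such a lean follows the dye or the genotypes is not settled, because the numerator of the ratio is not stated. The place of printing does not depend on the numerator and was checked only by block centring. The probes of rop9 and LOC542610 lay in the same block, and block centring took their spreads from 2.58 and 1.27 to 1.27 and 1.04. In simulated loops with balanced dyes and a fixed numerator channel, parental differences of 1 and 2 gave 1 sign in 0% of 100 probes each. Each simulated loop held effects of both signs by construction, so this 0% decides nothing about the genotypes as a source. In all, 48 of 18303 probes (0.262%) had 1 sign on at least 90% of arrays, 9 above and 39 below, against 0 after random sign changes. After each block was centred 8 probes had 1 sign, 4 of them among the 48. Most of the 48 thus no longer had 1 sign when block offsets were removed. Without S17 the number was 93, and without S25 it was 75, when 24 of 26 arrays sufficed.

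Over 351 pairs of arrays the correlation across probes had a median of -0.0047, from -0.443 (S15 and S22) to 0.552 (S20 and S22). Correlations lay below -0.3 in 6 pairs and above 0.3 in 5, and 253 pairs exceeded in size the largest value after shuffling, 0.0353. Probes are not independent replicates, and because neither the numerator nor the genotypes are known, the sign of a correlation has no settled meaning. The first component held 12.1% of the variance and the second 8.68%, together 20.8%, against 14.4% after shuffling. The first component alone held 8.10% after shuffling. Array S27 had a weight of 0.797 on the second component, where the next largest in size was -0.295 (S1). That component was thus mostly 1 array and is little evidence of structure shared by arrays. The highest block median on S27 was 3.33.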

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

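Centring, scale, the measure and threshold of spread, the number of arrays required and the left-out arrays were fixed before the data were examined, whereas block centring, repeated values as missing, each set of arrays alone, matched random lists and 1 value per gene were chosen after seeing the data. Requiring values on all 27 or on 5 arrays moved nothing, because all probes had all values. The list outside the central range kept its direction. Lists inside it changed side in several settings, for example with ratios of 0.963 for starch and 0.983 for oxidative stress genes with 1 value per gene, 0.926 for aquaporins within S1 to S15, and 0.959 to 1.02 for the cytoskeleton with an array left out. The number of probes with a spread of at least 2-fold was 4617 with the interquartile range and 9456 at a distance of 1.5, both stricter by construction, and 13999 to 14698 with an array left out. Probes with 1 sign numbered 1 when all arrays had to share it, 8 after block centring, 495 within S1 to S15 and 395 within S16 to S27, where fewer arrays have to match, and 49 to 93 with an array left out. The first 2 components held 23.7% without removal of probe medians, 27.4% within S1 to S15 and 41.2% within S16 to S27, where fewer arrays share the variance, and 20.2% to 22.4% with an array left out. Ratios of list medians to that of gene-named probes left the central range of random lists for oxidative stress genes with the interquartile range (1.17), for cell wall genes within S1 to S15 (1.38) and without S13 (1.26, range 1.14 to 1.28 with an array left out), and for phenylpropanoid genes with the interquartile range (2.31), rescaled arrays (2.43), block centring (2.51) and S1 to S15 (3.02), although among matched lists the phenylpropanoid percentile fell from 97.1 to 65.4. The root and metal list no longer stood outside that range with the interquartile range (1.09) or matched lists (3.84, percentile 92.8), and the cause was not tested. Of the other alternatives without a left-out array, 44 planned and 91 added values kept their side of the range or stayed within the limits set for each result. No paired analysis was possible because no array could be placed in a comparison of genotypes. No signal over background was used, so how far dim spots limit the spreads was not measured.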

Other observations

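Tests reported here were chosen after the results were seen, except the check of agreement within each set of arrays and both checks of the first component against repeated values. Genes of protein synthesis had narrow spreads from array to array, relative to random lists. Ribosomal proteins matched by symbol had a median spread of 0.98 over 78 probes of 16 genes, 0.842 times that of gene-named probes, at the 0.13th percentile of random lists and the 0.935th of lists matched on repeated values. Translation factors had 0.97 over 97 probes of 12 genes, 0.830 times, and 0 of 10000 random lists had a lower median. Probes of a gene are not independent members, and with 1 value per gene the percentiles were 0.20 for ribosomal proteins and 0.04 for translation factors. Single probes with wide spreads were those of LOC541668 (rpl30) at 4.31, LOC542339 (rpp3) at 3.69 and LOC542323 (rpp2) at 3.18. These probes had 4.87, 5.47 and 3.90 within S1 to S15, and 1.17, 1.72 and 1.38 within S16 to S27. The other rpl30 probe had 1.41. Over all probes of the gene the median spread was 1.19 for rpp3 (7 probes) and 0.92 for rpp2 (18 probes). The widest elongation factor probes were LOC542620 (elfa3) at 2.33 and LOC542581 (EF1A) at 2.18 and 1.97. The EF1A probe at 2.18 held a most frequent value on 16 arrays. After block centring the elfa3 probe had 1.38 and the EF1A probes had 2.26 and 2.03, so this order was not kept. With the interquartile range the ribosomal ratio was 0.907 and no longer outside the central range.

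Separate probes of the same gene tended weakly to vary together over arrays, and for a few genes they did so closely. The 6 probes of LOC542367 (GAPC1), cytosolic glyceraldehyde-phosphate dehydrogenase, lay in 6 blocks and had a mean pairwise r of 0.647 (rho 0.668), with 0.730 within S1 to S15 and 0.607 within S16 to S27. LOC541700 (pgd2), 6-phosphogluconate dehydrogenase, had 0.812 (rho 0.845) over 2 probes, and LOC542340 (rpp2b), an acidic ribosomal protein, had 0.812 (rho 0.875). LOC542617 (rps27), a ribosomal protein, had 0.831, which was 0.593 without S13 and S19, and the bZIP gene LOC542700 (lip15) had 0.634, which was 0.387 without S15 and S20. LOC100125656 had 0.755 over 4 probes, LOC100125640 (GRF2) had 0.563 over 5, LOC542113 (nfa101) had 0.549 over 2, which was 0.291 after block centring, and PER42, a peroxidase, had 0.495 over 3. These 9 genes reached 0.5 in each set of arrays, whereas shuffled gene names gave a median of 3 and a highest of 9. That number lay at the top of the shuffled range and did not exceed it. Over all arrays 17 genes reached 0.5 (highest shuffle 15), as did 24 after block centring over pairs in different blocks (highest 16), 31 within S1 to S15 (highest 25) and 24 within S16 to S27 (highest 26). No p-value over arrays is given, because arrays are unassigned and RNA pools are shared between arrays.

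Over the 258 genes with at least 2 probes, leaving out the uncertain name MNB1b, the mean agreement was 0.105, and 83 genes had a negative value. The paired probes of nas1, pal3 and me3, given above for their spreads, had -0.11, 0.03 and -0.21, so they did not vary together. Of the 25 genes with the widest probes, 12 had other probes. Among these, HRGP had 0.349, and piip1 had 0.392, which was 0.115 without S20 and S23. M8, pox2, cesa8 and 4CL had 0.21, 0.17, 0.17 and 0.11. Values were 0.10, 0.07 and 0.03 for hsp18a, CesA-9 and WRKY1, and -0.13, -0.17 and -0.31 for hsp22, aprl8 and HINT. Random pairing of probes is argued against, since the highest of 1000 shuffles of gene names gave 0.0635. Printing in the same block is argued against too, since block-centred values of pairs in different blocks gave 0.136, above the highest shuffle of 0.0677. A difference between the sets of arrays does not account for it, as the lower value within a set was 0.0872 (S16 to S27), above its highest shuffle of 0.0525. A candidate explanation that stays open is that these transcripts differed between the RNA pools on an array. No biological explanation was tested, because no array has a group. No intensity was used and the shuffles were not matched on signal, so the checks leave a part of signal level open as well.

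The named probes with the widest spread may owe it in part to signal near the floor. Of the 25, 20 held an array's most frequent value on at least 1 array, against 2.85 expected, but on S19, S21, S25 and S27 that value lies far from the centre and itself widens a spread. On the other 23 arrays alone the number was also 20, against 2.80 expected from the 11.2% of gene-named probes that did (one-sided hypergeometric p = 1.2e-15, across probes, which are not independent). Reading the value as a floor is an inference that these arrays allow and the other 4 do not. Variation of the transcripts themselves was checked through other probes of the same genes and was left open. The 29 other probes of 12 of these genes had a median spread of 1.31, against 5.46 for the 25. A lower value was fixed in advance, because the 25 were chosen as the widest. The median of 1.31 was at the 88.6th percentile of random probe sets, which decides neither way. What might make the transcripts vary was not tested.

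The first component of the arrays, with 12.1% of the variance, gave an area under the curve of 0.480 between probes that ever held a most frequent value and the others. That decides nothing, since probes with large values of both signs would give about the same. Probes at a most frequent value are argued against as its source by the other 14186 probes alone, on which the component held 18.9%, or 156.2% of its share, with array weights correlated at 0.967 with the original ones. Printing blocks are argued against as its source as well, because after block centring the component kept 104.0% of its share and its array weights correlated at 0.970 with the original ones. Both shares are of the variance left after each step, so they do not show how much of the component's own variance was kept. The argument rests on the array weights. What the first component follows stays open, and no biological explanation was tested.

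The numbers of probes at the array's most frequent value fell into separate clusters. From S1 to S15 they were 452, 2122, 2545, 1719, 1773, 1948, 2182, 1090, 2040, 1491, 1868, 748, 688, 1636 and 584. From S16 to S27 they were 63, 18, 22, 11, 70, 26, 50, 38, 46, 87, 65 and 73. The value itself lay far from the array's centre on S19 (4.02), S21 (6.11), S25 (-2.0) and S27 (4.70), on the log2 scale as deposited.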
